A study of Vitis labrusca x Vitis vinifera with 12 samples.

How the data were processed

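Total RNA (250 ng) from each of 12 samples was labelled with Cy3 and hybridised to a 1-colour array, per the labels. Spot intensity was read by the authors with Agilent Feature Extraction 9.5, per the submitters' processing notes. Per the file headers, the processed intensity of a spot had its background subtracted and its spatial trend removed, was not normalized between arrays, and carried a flag for signal well above background, for saturation and for outlier spots. The authors' deposited value table held log2 values. Set against the scanner intensities, each of its columns was the log2 processed signal plus 1 constant per array that brought the 75th percentiles to 9.72 on all arrays, and the origin of that common level is not given in the sources used here. Its column medians for replicates 1, 2 and 3 were 5.79, 5.67 and 5.68 at 15 °C in light, 5.87, 5.73 and 5.75 at 15 °C in darkness, 6.22, 6.09 and 6.08 at 35 °C in light, and 5.98, 5.86 and 5.90 at 35 °C in darkness. This table served as an alternative. Apart from outlier-flagged spots it matched the scaled values used below up to nearly 1 constant, so its results were bound to be nearly the same and add no support.

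Per the file headers, the arrays lay on 3 slides with 4 arrays each. The slide was the replicate number, so every slide held all 4 conditions, and each condition had its own place on every slide, so place and condition cannot be told apart. Each array had 45182 spots, of which 1417 were controls and 43765 were probes for berry transcripts, with 42999 distinct sequences. Of these probes 30072 were named after gene models and 13693 after cDNA or other sequences.

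Values were log2 of the processed intensity minus the 75th percentile of the array over non-control probes. Control spots and outlier-flagged spots were left out. Probes were tested when they were well above background on all 3 arrays of at least 1 condition, which kept 27791 (21352 were above background on all 12 arrays). A further 2 probes were left out for fewer than 2 unflagged spots in a condition. A model with 4 condition means was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and contrasts were called at a Benjamini-Hochberg adjusted p below 0.05. Differences are log2, with light minus darkness and 15 °C minus 35 °C. The interaction is light minus darkness at 15 °C, minus light minus darkness at 35 °C. Between spots of the same sequence on an array the SD was 0.088 over 347 sequences above background on all arrays, and the median SD between arrays of a condition was 0.125. Where a probe was not well above background on any array of a condition, its bound was computed with, per array, the higher of the lowest signal among probes above background and its own. On simulated data for light against darkness at 15 °C, over 27745 probes, the same fit and threshold recovered 78 of 100 probes changed 2-fold. They recovered 95 of 100 changed 4-fold, with 9 false calls. The simulated values were already scaled and filtered, had no slide effect and changed in only 200 probes. These figures therefore do not give the recovery or the false calls of the comparisons below.

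Lists of gene names were fixed before the data were examined, but the array files describe every probe as unknown and no table of names was used here, so these lists were not tested. The rule fixed for named genes also needed names: it took the widest changes past the threshold with no overlap between conditions. Here it was applied to gene-model probes above background on all 6 arrays compared (all 12 for the interaction), and at most 2 rises and 2 falls are given per comparison. In place of the name lists, probe sequences of gene models were translated in 3 forward frames and searched for conserved protein motifs. This list of 59 motifs was written after the files were seen and before any signal was compared. A motif was kept with at least 3 tested probes and with hits on the reverse strand at no more than 10% of its hits, which left 15 groups. A motif places a probe in a protein family and does not name a gene, and members of a family with near-identical sequences can share signal on these probes. The groups were tested with limma's camera against the other probes among 19917 gene-model probes, with a preset correlation of 0.01, and adjusted over 15 groups and 5 contrasts. With an estimated correlation no group passed the threshold. For small heat-shock proteins, chlorophyll a/b-binding proteins and expansins, counts of called members adjusted over the list alone were the same as those adjusted over all probes.

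Alternatives fixed before the data were examined were normexp background correction (offset 50) on the mean and background intensities, quantile and median scaling, the authors' table, other filters, outlier-flagged spots kept, the replicate number or slide as a block, other fits and thresholds, and leaving out each array or replicate number. Scaling to the spike-in controls (7 of 10 sequences with 32 spots each, those with a mean log2 signal of at least 6), the bounds for motif groups, and the fit of chalcone and stilbene synthase probes without replicate 3 at 35 °C in light were added after the data were seen. The spike-in scale moved the median difference of all tested probes to 0.24 for light at 15 °C, 1.44 for light at 35 °C, 0.57 for temperature in light, 1.72 for temperature in darkness and -1.17 for the interaction. On the main scale these medians were -0.12, -0.10, -0.16, -0.20 and 0.02. With normexp they were 0.25, -0.34, 0.24, -0.46 and 0.49, and with centring on the median of tested probes or quantile normalization they stayed between -0.25 and 0.17. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the motif search and the plots.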

Results

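Gene expression was measured in berries of the table grape 'Pione', a hybrid of Vitis labrusca and Vitis vinifera, detached as the first colour appeared on the skin. The berries were then kept for 10 days at 15 °C or 35 °C, in light or in darkness. These 4 conditions had 3 samples each, every sample being 15 berries whose total RNA was labelled with the dye Cy3 and hybridised to its own 1-colour oligonucleotide array. The layout crosses light with temperature, and the series title states its purpose as a search for transcripts that light or low temperature raises in ripening berries. Each array carried 43765 probes for berry transcripts, of which 30072 were named after predicted grape gene models. The array files give no gene names, so transcripts are described here by protein motifs encoded in their probe sequences, and a few probes by their identifiers. The labels do not say whether the 3 samples of a condition came from separate incubations, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays, 3 per condition, limits the precision, and the median standard error of a log2 difference between conditions was 0.12.

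The share of probes well above background was 60.8 ± 0.97% (SD, n = 3) at 15 °C in light, 59.8 ± 0.80% at 15 °C in darkness, 60.6 ± 1.11% at 35 °C in light and 55.7 ± 1.29% at 35 °C in darkness. No berry probe was saturated. The 75th percentile of log2 signal, to which all values below are relative, was 9.97 ± 0.24, 9.70 ± 0.09, 9.54 ± 0.19 and 8.52 ± 0.27 in the same order. The spike-in control RNAs moved the other way, at mean log2 signals of 13.67 ± 0.18, 13.75 ± 0.07, 13.97 ± 0.09 and 14.49 ± 0.27. Berries kept at 35 °C in darkness therefore had the dimmest berry probes and the brightest spike-ins on all 3 arrays, and counts on the spike-in scale are given beside several motif groups. Between arrays of a condition the probe levels correlated at 0.986 to 0.995, and between arrays of different conditions at 0.723 to 0.954.

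**Figure D1:**
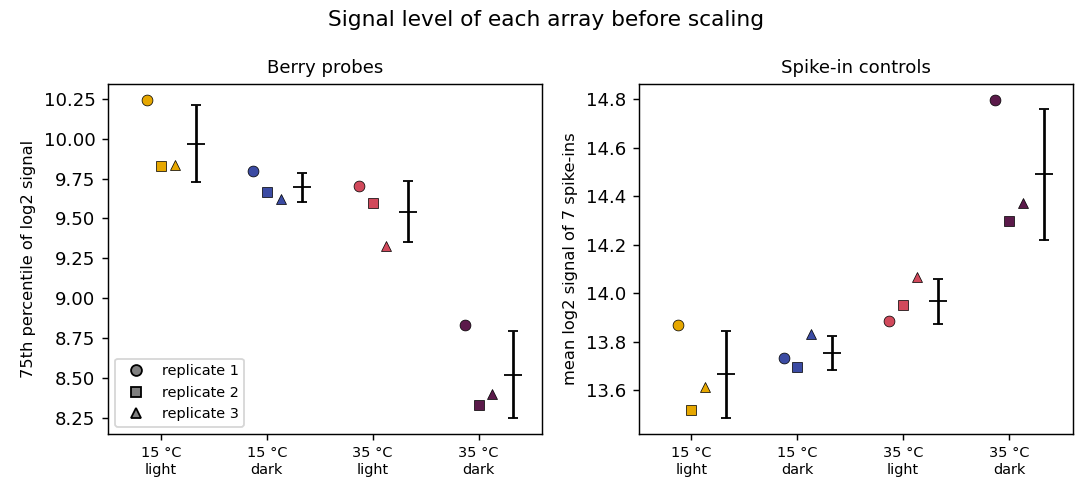
Signal of each array before scaling, by condition: left, the 75th percentile of log2 signal over berry probes, and right, the mean log2 signal of 7 spike-in controls. Each point is an array (the marker shape is the replicate number, which is also the slide), and the bars show the mean and SD of 3 arrays; at 35 °C in darkness the berry probes averaged 8.52 and the spike-ins 14.49.

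The first comparison asked which transcripts light changed at 15 °C. All 4 probes with a chlorophyll a/b-binding motif, found in the light-harvesting antenna proteins of photosynthesis, were higher in light, by 1.18 to 3.86 on the log2 scale. Their mean level was 5.29 ± 0.04 (SD, n = 3) in light and 2.93 ± 0.01 in darkness, and the difference was 2.31, 2.38 and 2.39 on slides 1, 2 and 3. The group stood above other gene-model probes with an adjusted p of 0.0042 by limma's camera at its preset correlation, and an adjusted p of 0.359 with an estimated correlation. Of the 9 probes with a small heat-shock protein motif, chaperones that bind unfolding proteins, 6 were lower in light and 1 was higher, by at least 1.46 (log2), its dark side being not well above background. On the spike-in scale 6 of the 9 differences were negative. The group did not pass the camera test, with an adjusted p of 0.077.

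Several other motif groups had calls in both directions or none at 15 °C. Among 12 probes with the sugar transporter motif of monosaccharide carriers, 5 were higher in light, 2 were lower and 5 did not pass the threshold. Of 4 laccase probes, copper oxidases known from lignin formation, 3 were higher and 1 was lower. Of 4 metallothionein probes, small cysteine-rich metal-binding proteins, 2 were higher, 1 was lower and 1 did not pass. Of 4 probes with an expansin motif, proteins that loosen cell walls, 1 was higher and 2 were lower. The 5 probes with the motif shared by chalcone and stilbene synthases, the entry enzymes of flavonoid and stilbene synthesis, differed by 0.15 to 1.03 and none passed the threshold. Their spread came from replicate 3 of berries at 35 °C in light, without which 4 of these 5 probes were called higher in light at 15 °C.

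Over the whole array, 15454 of 27791 tested probes differed between light and darkness at 15 °C by limma at an adjusted p below 0.05, and 6702 did with normexp background correction. Of these, 6379 were higher in light and 9075 were lower, and 2593 and 2403 of them changed at least 2-fold. The higher probes made up 41.3% of the calls, but 74.9% when arrays were scaled to the spike-ins. In 99.8% of the called probes the direction was the same on each of the 3 slides. Calling the probes on the same arrays largely fixes this share, here and in the comparisons below, so it adds no separate evidence. The 3 arrays of each condition did not overlap for 67.8% of all tested probes, where chance gives 10%. The probe with the widest rise among gene models above background on all 6 arrays, GSVIVT00019630001, was 7.96 ± 0.15 (SE) higher in light, at 3.50 ± 0.03 (SD, n = 3) against -4.46 ± 0.12, with 7.85 to 8.13 within slides (limma adjusted p = 2.1e-10). It was followed by GSVIVT00007710001 at 7.36 ± 0.22. The widest falls among the same probes were -5.53 ± 0.18 for GSVIVT00002585001 and -5.36 ± 0.19 for GSVIVT00023201001.

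At 35 °C, light raised the chlorophyll a/b-binding group again, with all 4 probes higher by 1.08 to 5.29. Their mean level was 4.56 ± 0.14 (SD, n = 3) in light and 1.30 ± 0.16 in darkness, and the difference within slides was 3.03, 3.16 and 3.61. Camera gave an adjusted p of 0.0193, which was 0.102 on the spike-in scale, where all 4 probes were still higher, and 0.359 with an estimated correlation. The small heat-shock protein group was lower in light, with 8 of 9 probes lower, 1 higher by 1.74, and the lowest at -7.39. Its mean level was 2.55 ± 0.16 in light against 5.66 ± 0.03 in darkness (camera adjusted p = 0.0056, and adjusted p = 0.385 with an estimated correlation). The mean difference was -3.19, -3.24 and -2.89 on the 3 slides and -1.56 when scaled to the spike-ins, where 8 of 9 probes stayed lower.

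All 4 expansin probes were called higher in light at 35 °C, by 0.30 to 6.09, but for 1 of them the dark side was not well above background and its bound was negative, so its direction is not established, and the group missed the camera threshold with an adjusted p of 0.084. With normexp background correction 3 of these 4 stayed higher. All 4 metallothionein probes were called lower, although on the spike-in scale 2 were lower and 2 higher, and the camera adjusted p was 0.113. Of these, 1 was not well above background in either condition, 1 was so in light only, and the others differed by -2.72 and -1.12. Of 12 monosaccharide transporter probes 9 were higher and 3 were lower (camera adjusted p = 0.382), and of 4 laccase probes 2 were higher and 1 was lower (adjusted p = 0.740), while all 4 laccase differences were positive on the spike-in scale. The 5 chalcone and stilbene synthase probes had a mean difference of 0.83 and none passed the threshold. On slides 1 and 2 they averaged 2.69 and 2.63 higher in light, and on slide 3 they averaged -2.84. Without replicate 3 at 35 °C in light, all 5 were called higher.

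**Figure D2:**
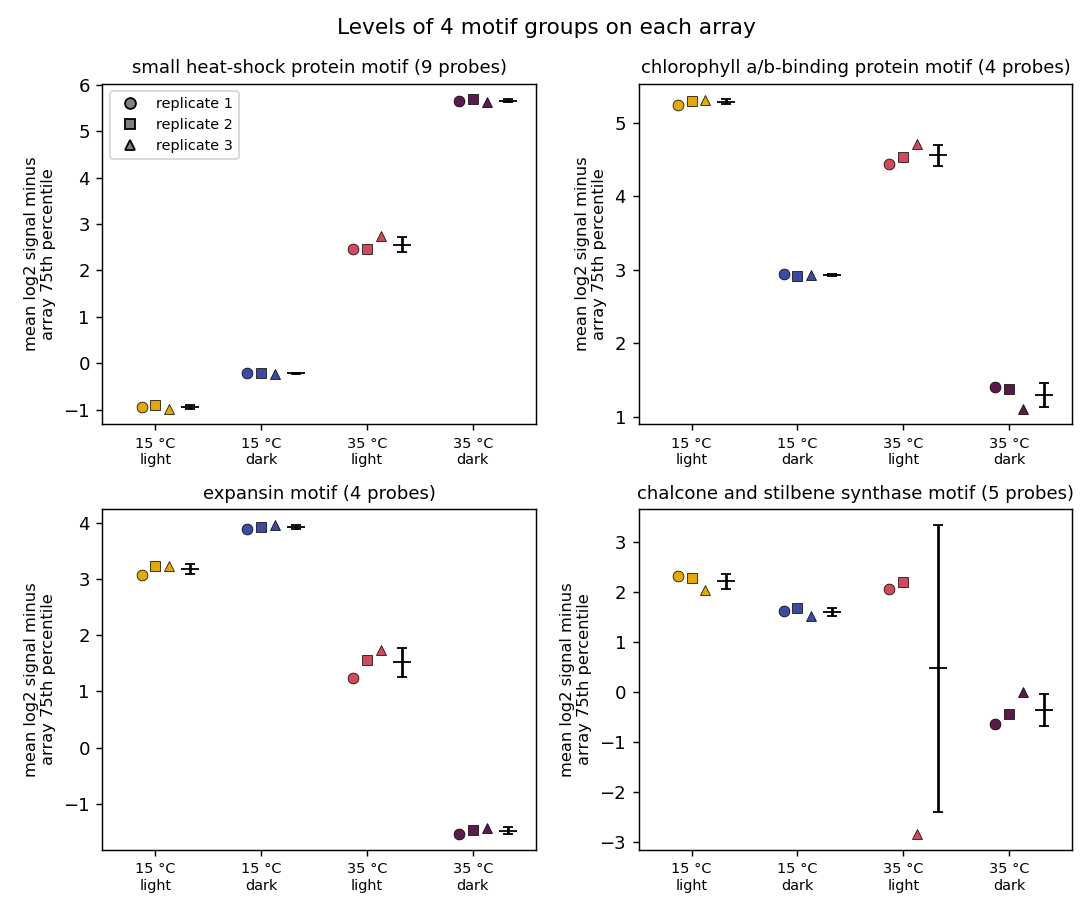
Mean level of the tested probes of 4 motif groups on each array, as log2 signal minus the array's 75th percentile. Each point is an array, the marker shape is the replicate number, and the bars show the mean and SD of 3 arrays; small heat-shock protein probes averaged 5.66 at 35 °C in darkness and -0.93 at 15 °C in light, and replicate 3 at 35 °C in light lies apart for chalcone and stilbene synthase.

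Light changed 21009 probes at 35 °C by limma, 9555 higher and 11454 lower, of which 5649 and 5410 changed at least 2-fold. The count with normexp was 10611. Higher probes were 45.5% of the calls on the main scale and 93.5% on the spike-in scale. For 2307 of the called probes one side was not well above background on any array. The size of their fitted folds, which the 2-fold counts use, is thus not established. Nor is the direction where the bound has the opposite sign, as for a called expansin probe (0.85, bound -0.80) and a called class III peroxidase probe (-1.89, bound 0.37). How many other calls this touches is not known, since bounds are given only for members of motif groups. A bound sets the bright condition's mean against, on each dim array, the higher of the lowest signal among probes well above background and the probe's own. The direction was the same on all 3 slides for 99.1% of the calls, and 75.7% of tested probes had no overlap between the conditions, against 10% by chance. GSVIVT00029417001 was 7.67 ± 0.07 (SE) higher in light, at 5.26 ± 0.05 (SD, n = 3) against -2.41 ± 0.10 (limma adjusted p = 1.3e-12), and GSVIVT00017430001 was 7.54 ± 0.07 higher. GSVIVT00018325001, which carries the small heat-shock protein motif, was -7.39 ± 0.15 lower, and GSVIVT00024724001 was -7.27 ± 0.30 lower. The log2 differences for light at 15 °C and at 35 °C correlated at r = 0.344 (Spearman's rho 0.309) across probes, which are not independent replicates.

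The second factor was temperature. In light, berries kept at 15 °C had lower small heat-shock protein signals than berries kept at 35 °C for 8 of 9 probes, by up to -6.01, while 1 probe was 0.67 higher. The group mean was -0.93 ± 0.04 (SD, n = 3) at 15 °C and 2.55 ± 0.16 at 35 °C, with a difference of -3.39, -3.34 and -3.71 on the 3 slides, and of -3.26 with 1 dim member at its bound. Camera gave an adjusted p of 0.0042, and an adjusted p of 0.362 with an estimated correlation. With normexp background correction 7 of the 9 were lower. All 4 metallothionein probes were higher at 15 °C, by 0.36 to at least 8.15, with levels averaging 0.95 ± 0.18 against -3.46 ± 0.16. For 2 of these 4 the 35 °C side was not well above background, and with them at their bounds the mean difference was 3.33 (camera adjusted p = 0.084, not past the threshold). The mean was 2.24 with normexp and 5.13 on the spike-in scale, with all 4 higher on both. All 4 expansin probes were higher by 0.23 to 4.67 (camera adjusted p = 0.146).

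Of 12 monosaccharide transporter probes 8 were higher at 15 °C in light and 2 were lower (camera adjusted p = 0.098). Of 4 laccase probes 3 were higher, by up to 6.21, and 1 was lower by -2.94 (adjusted p = 0.256). Chlorophyll a/b-binding probes differed less, with 3 of 4 higher and a mean difference of 0.72 (adjusted p = 0.328). Of the 5 chalcone and stilbene synthase probes 2 were called higher and none lower, but without replicate 3 at 35 °C in light 2 were higher and 3 were lower (camera adjusted p with all arrays = 0.616).

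In total 21981 probes differed between 15 °C and 35 °C in light by limma, 9684 higher and 12297 lower at 15 °C, with 5339 and 7220 of them at least 2-fold. The count with normexp was 11946. Higher probes were 44.1% of the calls, and 70.9% on the spike-in scale. The direction held on each slide for 99.3% of the calls, and 81.4% of tested probes showed no overlap between the conditions, against 10% by chance. GSVIVT00033069001 was 9.33 ± 0.13 (SE) higher at 15 °C, at 6.43 ± 0.03 (SD, n = 3) against -2.90 ± 0.31 (limma adjusted p = 8.2e-12), and GSVIVT00009886001 was 8.97 ± 0.16 higher. GSVIVT00001179001 differed by -9.49 ± 0.17 and GSVIVT00026965001 by -8.90 ± 0.16.

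In darkness, all 9 small heat-shock protein probes were lower at 15 °C, with differences from -2.97 down to a bound of -8.50. Their mean level was -0.21 ± 0.01 (SD, n = 3) at 15 °C and 5.66 ± 0.03 at 35 °C, and the difference was -5.86, -5.89 and -5.85 on the 3 slides. It was -3.96 on the spike-in scale, with all 9 lower, and -5.40 with the 2 members not above background on a side set at their bounds. Camera gave an adjusted p of 0.0010, and an adjusted p of 0.359 with an estimated correlation. All 4 expansin probes were higher at 15 °C in darkness, by 2.77 to 7.03, from a mean level of -1.48 ± 0.06 to 3.93 ± 0.04, or by a mean of 4.99 with 1 dim member at its bound. Here camera gave an adjusted p of 0.0212, which was 0.214 without the filter on dim probes, 0.126 on the spike-in scale and 0.359 with an estimated correlation.

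Of 12 monosaccharide transporter probes 9 were called higher at 15 °C in darkness, 1 of them with a 35 °C side not well above background and a bound of -0.73, so that its direction is not established. The lower calls were 2, 1 of them with a bound of -5.08 and the other not well above background at either temperature (camera adjusted p = 0.091). On the spike-in scale 11 of these 12 differences were positive, as they were for temperature in light and for light at 35 °C. Of 4 chlorophyll a/b-binding probes 3 were higher and 1 was lower by -0.87, which was higher on the spike-in scale (adjusted p = 0.321). Of 4 laccase probes 3 were higher, 1 of them by at least 7.09 and 1 not well above background at either temperature, and 1 was lower, with 2 higher and 2 lower under normexp and all 4 higher on the spike-in scale (adjusted p = 0.321). Metallothionein probes split, with 2 higher by up to 6.72 and 1 lower, but all 4 positive on the spike-in scale (adjusted p = 0.559). Of the 5 chalcone and stilbene synthase probes 2 were called higher and all 5 had positive differences, from 0.30 to at least 5.48 (adjusted p = 0.640). Without replicate 3 at 35 °C in light, which enters the shared spread, 3 were called higher.

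Among the 4 comparisons of 2 conditions, temperature in darkness gave the highest count, 23350 probes by limma, 10541 higher and 12809 lower at 15 °C, with 7178 and 8337 at least 2-fold. The count with normexp was 14581. Higher probes were 45.1% of the calls, and 88.5% on the spike-in scale. The direction held on each slide for 99.7% of the calls, and 84.9% of tested probes showed no overlap against 10% by chance. For 3068 calls 1 side, and not both, was not well above background on any array. GSVIVT00022146001 was 9.19 ± 0.11 (SE) higher at 15 °C, at 5.24 ± 0.11 (SD, n = 3) against -3.95 ± 0.14 (limma adjusted p = 1.6e-12), and GSVIVT00027235001 followed, at 8.36 ± 0.03 against -0.64 ± 0.28. GSVIVT00001179001, also named in light, differed by -12.9 ± 0.17, and GSVIVT00028165001 by -10.9 ± 0.11. The temperature differences in light and in darkness correlated at r = 0.713 (Spearman's rho 0.710) across probes.

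**Figure D3:**
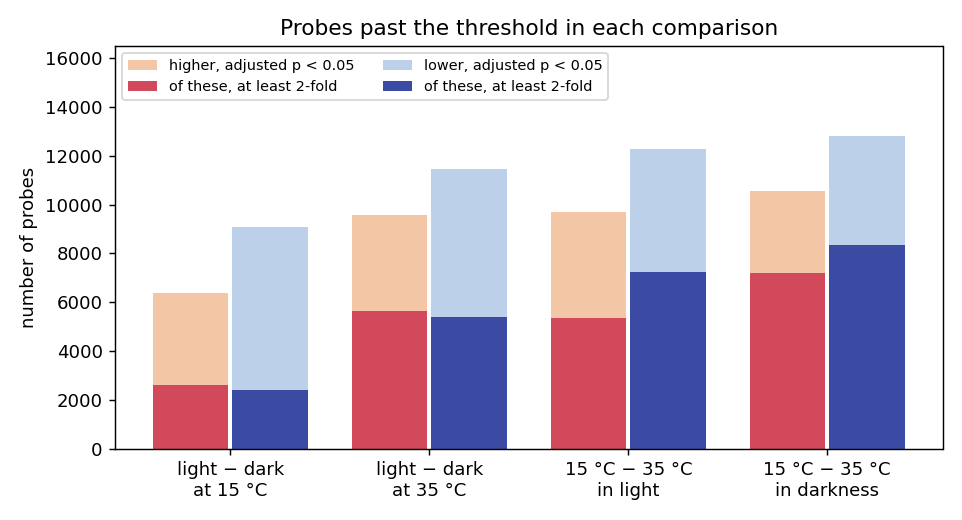
Number of probes past limma's adjusted p of 0.05 in each comparison of 3 against 3 arrays, with higher probes in the left bar and lower probes in the right bar of each pair, and the part changed at least 2-fold in the darker shade. Light at 15 °C gave 15454 probes and temperature in darkness 23350.

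The interaction asked whether the light difference at 15 °C departed from that at 35 °C. It did so for the small heat-shock proteins, for which the light difference was 2.39 higher at 15 °C than at 35 °C in the mean, with 7 of 9 probes past the threshold and all 7 in that direction. The difference was 2.47, 2.55 and 2.14 on the 3 slides, it averaged 1.77 over the 7 probes above background in every condition, and on the spike-in scale 7 of 9 probes stayed positive. Camera gave an adjusted p of 0.0081, which was 0.0561 with quantile normalization, 0.0564 over probes above background on all arrays, and 0.393 with an estimated correlation. Expansins went the other way, with all 4 probes past the threshold at -5.73 to -1.85. For 1 of them the dark condition at 35 °C was not well above background, so the size of its interaction is not established, and the other 3 averaged -4.37. Camera gave them an adjusted p of 0.0147, which was 0.143 without the filter on dim probes and 0.359 with an estimated correlation. With normexp 3 of these 4 kept the negative sign.

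All 4 metallothionein probes had a positive interaction, 2 of them with a condition not well above background, with 3 of 4 positive on the spike-in scale and a camera adjusted p of 0.099. The chlorophyll a/b-binding probes had 1 positive and 2 negative calls (adjusted p = 0.596), the laccases 1 and 2 (adjusted p = 0.623) and the monosaccharide transporters 2 and 5 (adjusted p = 0.822). The transporter mean of 0.43 included 1 probe at 8.21 that was not well above background at 15 °C in darkness. Over the 9 transporter probes above background in every condition the mean was -0.47. On the spike-in scale the mean of all 12 was -0.75, with 11 of 12 negative. No chalcone and stilbene synthase probe passed the threshold, but without replicate 3 at 35 °C in light all 5 were negative and called, with a mean of -1.88 (camera adjusted p with all arrays = 0.975).

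By limma 18234 probes had an interaction past the threshold, 9184 positive and 9050 negative, and 7718 did with normexp. Positive ones were 50.4% of the calls, but 8.4% on the spike-in scale. Among gene-model probes above background on all 12 arrays, GSVIVT00026513001 had the widest positive value, 7.04 ± 0.22 (SE), since it was 0.74 higher in light at 15 °C and -6.30 lower at 35 °C (limma adjusted p = 4.9e-09). GSVIVT00002585001 had the widest negative one, -6.72 ± 0.25, at -5.53 for 15 °C and 1.19 for 35 °C.

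Averaged over temperatures, light changed 20520 probes by limma, 8856 higher and 11664 lower, and averaged over light conditions, 15 °C changed 24064 probes, 10757 higher and 13307 lower, against 10396 and 15062 probes with normexp. Higher probes were 43.2% and 44.7% of these calls, but 92.1% and 82.9% on the spike-in scale. Light and low temperature both raised 5542 probes (2711 with normexp), where independent lists would share 3428, and both lowered 7814, where independent lists would share 5585. The arrays at 35 °C in darkness lie on the same side of both averages, so a change in that condition alone adds to both overlaps, and independence is not their value without a joint effect. On the spike-in scale 17027 probes were raised by both. The calls for light at the 2 temperatures shared 3668 higher and 5144 lower probes, against 2193 and 3740 for independent lists, while 1558 were higher at 15 °C and lower at 35 °C and 2195 the reverse. The temperature calls in light and in darkness shared 7236 higher and 9414 lower probes, against 3673 and 5668 for independent lists.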

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

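The tests of the spike-in level, of the signal share of abundant probes, of the amount of berry mRNA, of the scale and of a wrong label were chosen after those results were seen, and the others were fixed before theirs were.

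An interaction of light and temperature passed limma's threshold for 18234 probes (7718 with normexp background correction). It was tested as the difference between the light effects at the 2 temperatures. The arrays at 35 °C in darkness enter this difference. The amount or quality of their RNA, weighed below, therefore stays open here too as an explanation. On the spike-in scale the median of this difference over all tested probes was -1.17, against 0.02 on the main scale. Among motif groups, camera on this difference singled out the small heat-shock proteins, whose light difference at 15 °C minus that at 35 °C lay 2.44 above other probes, and the expansins, at -3.68 against other probes (camera adjusted p = 0.0081 and 0.0147, and adjusted p = 0.393 and 0.359 with an estimated correlation). The limma test also picked out GSVIVT00026513001 at 7.04 and GSVIVT00002585001 at -6.72. In 1 of 100 splits of the 12 arrays, the real one, as many as 18234 probes were called, and the highest other split gave 4308. Splits drawn at random mix arrays of different conditions, which widens the spread within groups. They therefore set the count against no difference between any conditions, and do not test the interaction by itself.

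The light response was larger at 35 °C than at 15 °C, with 11059 against 4996 probes called and changed at least 2-fold. A signal floor on the dimmer arrays would shrink this ratio among bright probes, but among the 10675 brightest of those above background on all 12 arrays it was 2.67 (3669 against 1373). The choice of scale would bring the ratio near 1 under some setting. Over 5 settings, the scalings and normexp background correction, the lowest was 2.08 with normexp, and among the scalings it was 2.21 on the main scale. These values argue against both explanations as the whole cause. A larger transcript response to light in warm berries may account for it, as a hypothesis found and tested on the same arrays, and the amount or quality of the RNA at 35 °C in darkness, weighed next, stays open as another explanation.

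A signal outside the main measurement was the spike-in controls, 0.69 (log2) higher on the 3 arrays of berries at 35 °C in darkness than on the other 9, while the 75th percentile of berry probes differed by -1.22. A uniform loss of signal on these arrays, or at their place on the slide, would lower the spike-ins too, but they were higher by 0.69. A few abundant transcripts taking more of the signal would imply a difference of -0.071 for all other probes (100 brightest probes at 23.4% of the signal against 19.5%), far short of the fall. RNA degradation stays open, since probes that do not end at a stop codon fell less than probes that do by 0.096 at matched signal, too little to decide, and the distances of probes from the transcript end are not known here. Less berry mRNA per unit of spike-in stays open too, since the gap between berry probes and spike-ins, -1.91, only adds up the observations that make the pattern, and the RNA input and its quality were not tested apart from it.

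The chalcone and stilbene synthase probes of replicate 3 at 35 °C in light were low, at a mean of -1.66 for the 4 probes above background on all arrays, against 3.00 and 3.22 on replicates 1 and 2. This array had 110 probes at least 2 (log2) below both other replicates while these lay within 1 of each other, and no other array had more than 9. A local defect of the array would lower neighbouring spots, but the median deviation of 1602 tested spots within 2 rows and 2 columns of these 110 was 0.0035. This median speaks against a defect around most of the 110 spots. It cannot exclude 1 at a few of them, since neighbours of the chalcone and stilbene synthase spots were not examined apart. The array also had 34 outlier-flagged spots, against at most 19 on another array. A wrong label or RNA of another condition mixed in would leave levels within the range of the other conditions, but all 4 probes above background on all arrays lay below each of the other 11 arrays, and the array correlated at 0.986 or more with its own condition and at most 0.877 with another. What set this sample apart stays open, and no biological explanation was tested, since the labels describe the 3 samples alike.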

How the results depend on the processing

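Scaling to the spike-ins, the bounds of motif group members and the fit of chalcone and stilbene synthase probes without replicate 3 at 35 °C in light were chosen after the results were seen, and the motif groups after the array files were seen but before any signal was compared. The named probes kept their direction and their side of the threshold in all 440 of the alternatives that tested them. They were chosen as the widest changes in these data, so this says little about other called probes. The authors' table, among these alternatives, was bound to give nearly the main result. With normexp background correction fewer probes were called: 6702 for light at 15 °C, 10611 for light at 35 °C, 11946 for temperature in light, 14581 for temperature in darkness, 7718 for the interaction, 10396 and 15062 for average light and temperature, and 2711 raised by both; the cause was not tested. Requiring at least a 2-fold change left 4996, 11059, 12559, 15515, 10329, 6684, 13787 and 1941 in the same order, by its construction. On the spike-in scale 17027 probes were raised by both against 5542, since that scale lifts the median of all probes in light and at 15 °C. Without the filter on dim probes the share of higher calls fell to 31.1% for light at 35 °C, 32.2% for temperature in light and 30.3% in darkness. With normexp it was 54.8% for temperature in light.

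Other counts stayed within 1.5 times the main ones. Leaving out arrays or replicate numbers gave 11368 to 14183 for light at 15 °C, 18332 to 20621 for light at 35 °C, 19568 to 21480 and 21498 to 22946 for temperature in light and in darkness, 14334 to 18114 for the interaction, 17835 to 20393 and 22474 to 23950 for the averages, and 4841 to 5592 raised by both. Same-numbered arrays lay on the same slide, and their deviations from the condition means correlated at 0.094 to 0.589 (17 of 18 pairs over 0.1). The median for different numbers was -0.215, but centring on the condition means makes these negative when same-numbered arrays correlate, so it is no baseline. In 12 of 12 arrays the best correlation was with an array of their own number. The slide is thus a batch shared by arrays of all conditions, which the block takes into account, but the labels do not say that the number marks more than a replicate, and 1 pair missed the criterion of 0.1. With the replicate block the counts were 17914, 22553, 23284, 24418, 20429, 22053, 24947 and 5927, and no group call changed. The 8 motif group calls kept their side in 156 alternatives and missed the threshold in 14, with none reversed: 8 with an estimated correlation, 2 without the filter, 2 on the spike-in scale, 1 with quantile normalization and 1 over probes above background on all arrays. Median scaling, spike-in scaling and the authors' table differ from the main scale by 1 constant per array, which shifts all probes alike. They cannot reverse a group's difference from other probes, so the absence of reversals there was fixed in advance. The same holds for the estimated correlation. Apart from the estimated correlation, the highest adjusted p was 0.0171 and 0.102 for chlorophyll a/b-binding proteins in light at 15 °C and 35 °C, and 0.0225, 0.0171, 0.0058 and 0.0564 for small heat-shock proteins with light at 35 °C, temperature in light and in darkness, and the interaction. It was 0.214 and 0.143 for expansins with temperature in darkness and the interaction. Averaging probes of a gene was not run, since each probe has its own name. Signal over background limits the folds of called probes with a dim side, 820, 2307, 1862 and 3068 in the 4 comparisons of conditions.

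Splits of the 6 arrays of a comparison are too few, at 10, for a share under 0.05. In each, 1 split, the real one, gave the highest count, with 15454 against 1 in the highest other split for light at 15 °C, 21009 against 1 for light at 35 °C, 21981 against 0 for temperature in light and 23350 against 0 in darkness. Over 100 splits of the 12 arrays, 1 split, the real one, was as high for average light (20520 against 4010) and average temperature (24064 against 17420). The same held for probes raised by both (5542 against 1863). As for the interaction, these splits mix conditions, so they speak only against no difference between any conditions.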

Other observations

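The tests on the spike-in scale, the bounds and the count of probes apart on single arrays were chosen after results were seen, and the motif groups after the array files were seen but before any signal was compared.

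In motif groups of basic cell functions many probes were called lower in light on the main scale, and none of these groups passed the camera test. Of 8 ribosomal P protein probes, parts of the ribosome stalk, 6 were called lower in light at 15 °C and 7 at 35 °C (camera adjusted p = 0.064 and 0.181). On the spike-in scale 3 and 8 of these 8 differences were positive, and with quantile normalization 4 at 35 °C. Actin probes, of the cytoskeleton, had 3 of 5 and 5 of 5 lower (camera adjusted p = 0.146 and 0.107), where 2 and 5 were positive on the spike-in scale and 2 at 35 °C with quantile normalization. All 3 tubulin probes, of microtubules, were lower in light at 15 °C under all 5 settings (the scalings and normexp), with a mean of -0.73 on the main scale (camera adjusted p = 0.091). At 35 °C 2 were lower and 1 was higher, with the mean of -0.26 turning to 0.21 with quantile normalization and 1.29 on the spike-in scale, where all 3 were positive (camera adjusted p = 0.760). The 3 probes with the domain of WRKY factors, transcription factors known from stress and defence responses, were all lower in light at 35 °C, and lower at 15 °C than at 35 °C in darkness (camera adjusted p = 0.108 and 0.101). On the spike-in scale 2 and 1 of these 3 differences were positive.

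Of 13 probes with the calcium-binding EF-hand loop, 9 were lower in light at 35 °C and 1 was higher, while on the spike-in scale 9 had positive differences (camera adjusted p = 0.149). Of 7 protein kinase probes 4 were lower and 1 higher in light at 15 °C, and 1 was lower and 4 higher at 35 °C (camera adjusted p = 0.503 and 0.491). With spike-in scaling 4 of the 7 differences were positive at 15 °C and all 7 at 35 °C, and with normexp the means were 0.09 and -0.09. Their light difference had a negative interaction call for 5 and a positive one for 1 (camera adjusted p = 0.215), but with normexp 4 of the 7 were positive, and on the spike-in scale all 7 were negative. The 4 WD40 repeat probes, a protein-binding fold, averaged -0.20 to -0.04 over the 5 contrasts on the main scale, but light at 35 °C averaged 1.38 on the spike-in scale. Of 6 class III peroxidase probes, enzymes that oxidise phenolics at the cell wall, 3 were called lower in light at 35 °C and 1 higher, the latter not well above background in either condition, and 1 of the lower calls had a light side not well above background and a bound of 0.37, so its direction is not established (camera adjusted p = 0.598). Their mean difference there was -0.80 and -0.76 on slides 1 and 2 and -3.13 on slide 3, which holds the array that stood apart for chalcone and stilbene synthase.

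The arrays of slide 1 also differed in a small set of probes. On each of its 4 arrays 53 to 62 probes lay at least 2 (log2) above both other replicates while these lay within 1 of each other, against 9 to 36 on the other 8 arrays.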
